A study of Mus musculus with 18 samples.

How the data were processed

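RNA from mammary tumours of mice that carry an ERBB2 (neu) transgene was measured on 18 single-colour Affymetrix arrays, 1 array per tumour by the labels. Per the labels, 10 tumours came from mice lacking Snai2 (KO) and 8 from mice with intact Snai2 (WT). Total RNA was extracted with Trizol, then fragmented and biotinylated with a kit for whole-transcript arrays, per the labels' protocols. Each mouse was parous or nulliparous and had or lacked metastasis, which gave 6 groups. No WT tumour came from a mouse without metastasis, so genotype and metastasis status are partly confounded by design.

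The deposited table holds log2 expression values of 35556 probe sets on each array. RMA and the oligo package are named by the submitters' processing notes, with versions not given in the sources used here; RMA corrects background, normalizes arrays by quantiles and summarises the probes of a probe set. Array medians of these log2 values lay between 7.60 and 7.67. Values ran from 3.99 to 14.62. RMA values of dim genes are compressed, so fold changes of dim genes such as Snai2 may be understated, and quantile normalization removes any shift shared by all genes. An array gives no read depth, and the number of arrays limits the precision.

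Probe sets were named through the platform annotation. Of the 35556 probe sets, 21789 had 1 gene, 1621 had several and 12146 had none in that annotation; the last 2 kinds were left out of the main tests. For each gene the probe set with the highest mean was kept, which left 19938 genes. Symbols were checked through Entrez identifiers against RefSeq genes of GRCm38.p6, where 19855 of these genes matched. That table was used for names, chromosomes and gene order alone, since the build behind the platform annotation is not given in the sources used here. The tests placed 19844 genes on chromosomes 1 to 19 and X.

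Replicates were compared before averaging. Replicates 2 and 3 of KO parous mice with metastasis were nearly identical. Over 10252 genes with a mean log2 of at least 8, the SD of their difference was 0.102, against 0.285 for the next closest of 153 pairs of arrays and 0.705 for the widest. Their Pearson r across genes was 0.9986, against 0.9919 for the next highest pair. An array has no counting noise to set this against, but the pair differed far less than any other, so its mean was used as 1 sample. All tests therefore rest on 17 samples, with 2 in that group. The design fixed beforehand had all 18 arrays in the fits; the averaging was decided after the pair was seen, and the fit with both arrays kept apart is given as an alternative. The labels call the arrays biological replicates, so the tests measure the spread between tumours.

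Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold in each of 8 comparisons. Direct contrasts used a fit of 6 group means, which share 1 estimate of the spread. Additive fits used genotype, parity and metastasis status together. The difference of the parity contrasts was KO without metastasis minus WT with metastasis. Before the data were examined, 26 gene lists for cell types, processes, sample handling and the neighbours of Snai2 on chromosome 16 were fixed, of whose 620 entries 579 were matched. Lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the 26 lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance. Beside the count over all genes, members passing when adjusted over the list alone are given. A list score is the mean log2 value of its members in a sample.

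The rule for named genes was also fixed beforehand. It took Snai2 and Erbb2, the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, and up to 4 passing members of each list. Where fewer than 10 genes passed, it took the 5 smallest p-values in each direction, named as not passing. Predicted genes were counted and not named.

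Single values were compared with exact permutation tests (2-sided). The whole chromosome analysis, with its window size and the limit of 0.2 for a shifted window or chromosome, was chosen after the data were seen: the dimmest 40% of genes were left out, genes were put in order along each chromosome, and 120 windows of 93 to 110 consecutive genes were formed. The level of a window or chromosome in a tumour is the median deviation of its genes from the mean of the 17 samples. Enrichment of called genes on a chromosome was tested with Fisher's exact test against all placed genes and adjusted over the 20 chromosomes.

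The limma fits and the camera test at the preset correlation were tested on simulated data of the 19938 genes. Noise was drawn independently for each gene, so genes that move together were not simulated. The chromosome analysis, the permutation tests, fry and the estimated correlation were not tested this way. For parity in WT mice, 86.6% of genes changed by 1 log2 unit and 49.3% of those changed by 0.5 were recovered. For genotype in the additive fit the shares were 89.6% and 52.2%, and for genotype among parous mice with metastasis 73.1% and 37.3%. For the difference of the parity contrasts they were 67.2% and 25.4%, and there a list shifted by 0.5 missed the threshold, with an adjusted p of 0.0550.

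Alternatives fixed beforehand were all probe sets, leaving out dim genes, the mean of all probe sets of a gene, array medians subtracted, quantile normalization again, a trended and robust spread, array weights, the replicate number as a block, composition covariates (adipocyte and leukocyte list means), other thresholds, fewer groups in the fit, and leaving out each sample. The closing section gives their effect.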

Results

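Gene expression was measured in mammary tumours of ERBB2 transgenic mice with and without Snai2, a zinc finger transcription factor known for its part in epithelial-mesenchymal transition. The arrays cover KO parous mice with metastasis (3 arrays, 2 samples after the near-identical pair was averaged), KO parous mice without metastasis (3), a KO nulliparous mouse with metastasis (1), KO nulliparous mice without metastasis (3), WT parous mice with metastasis (4) and WT nulliparous mice with metastasis (4). The design asks whether the loss of Snai2, a history of pregnancy and metastasis go with differences in tumour expression.

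Snai2 expression was lower in tumours of KO mice. Its mean log2 value was 6.54 ± 0.17 (SD, n = 9) in KO and 6.84 ± 0.17 (SD, n = 8) in WT tumours, and the difference of -0.31 had an exact permutation p of 0.00247 over 24310 splits. Among mice with metastasis alone the difference was -0.32 (exact permutation p = 0.0182, 165 splits). Both tests pool parous and nulliparous mice. In the limma contrast among parous mice with metastasis the difference was -0.23 (SE 0.16, adjusted p = 0.929). In 7 of 9 KO samples Snai2 lay below the lowest WT sample. On every array it was dim, at most at the 35.4 percentile of genes, and whether its probes lie in the deleted part is not known here. Erbb2 was bright in both genotypes, with 12.81 ± 0.11 (SD, n = 9) in KO and 12.71 ± 0.14 (SD, n = 8) in WT tumours (exact permutation p = 0.137). Whether its probes read the transgene, the mouse's own gene or both is not known here. In the comparisons of parity and metastasis neither gene passed: log2 differences lay between -0.09 and 0.09 for Snai2 and between -0.11 and 0.09 for Erbb2.

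Tumours of KO and WT mice did not differ in any tested gene at the threshold. In the additive fit the gene with the smallest p was Kctd12b, which encodes an auxiliary subunit of GABA-B receptors. Its log2 difference was -1.57 (SE 0.26, adjusted p = 0.399), KO minus WT. Among genes with higher values in KO, Slc39a14, a zinc and iron transporter, stood at 1.11 (SE 0.25, adjusted p = 0.95), and Ppp3cc, a catalytic subunit of calcineurin, at 0.58 (SE 0.11, adjusted p = 0.756). Snai2 itself stood at -0.32 (SE 0.12, adjusted p = 0.999) when adjusted over all genes. Of the endothelial markers 18 of 19 lay below 0, with a median of -0.38, and camera called the list (adjusted p = 5.65e-06), but its adjusted p was 0.789 with an estimated correlation. No member passed over all genes and 1 passed when adjusted over the list alone. B and plasma cell markers had a median of 0.11 (camera adjusted p = 0.000112, adjusted p = 0.789 with an estimated correlation), with 0 of 15 members passing either way. That direction came from the lone nulliparous KO tumour with metastasis: without it the median was -0.08 and the call ended, and without the averaged KO replicates it was 0.20. The 62 measured neighbours of Snai2 on chromosome 16 had a median of 0.02 (camera adjusted p = 0.0247, adjusted p = 0.789 with an estimated correlation), with 0 members passing over all genes or when adjusted over the list alone. Their median ran from -0.02 to 0.07 with samples left out, and the call ended without KO parous replicate 1 or the averaged pair, both with metastasis, or without parous WT replicates 1 or 2. In all, camera called 9 of 26 lists and 0 with an estimated correlation. By limma, 0 genes passed and 885 of 19938 had an unadjusted p under 0.05.

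Among parous mice with metastasis, again no gene passed between KO (n = 2) and WT (n = 4). Among the genes with the smallest p in each direction were Sectm1a at 2.52 (SE 0.45), Tmem229b at 1.37 (SE 0.25), Hsf2bp at 1.33 (SE 0.22) and Kctd1 at 0.86 (SE 0.15), higher in KO, and Crim1 at -1.13 (SE 0.22) and Mycn at -0.58 (SE 0.11), lower in KO, each with adjusted p = 0.325. Mycn is a transcription factor of the Myc family. Endothelial markers lay below 0 in 19 of 19 members (median -0.25, camera adjusted p = 0.0312, adjusted p = 0.995 with an estimated correlation) and 0 passed over all genes or when adjusted over the list alone. The camera call on them ended without KO replicate 1 (median -0.24), the averaged KO replicates 2 and 3 (-0.21), WT replicate 1 (-0.24) or WT replicate 2 (-0.10). Neighbours of Snai2 had a median of 0.09 (camera adjusted p = 0.000172, adjusted p = 0.986 with an estimated correlation), with 45 of 62 above 0 and 0 passing either way; without KO replicate 1 the median was 0.04. In all, camera called 4 of 26 lists and 0 with an estimated correlation. With limma 0 genes passed and 1142 had an unadjusted p under 0.05. Leaving out replicate 1 of the KO group gave 2 genes, and leaving out the averaged replicates 2 and 3 gave 17, each time with a lone KO sample assumed to vary like the other groups.

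In WT mice with metastasis, tumours of parous mice had lower levels of interferon-stimulated and antigen presentation genes than tumours of nulliparous mice. Of 19938 genes, 370 fell and 108 rose in parous mice (n = 4 in each group, limma, adjusted p under 0.05), of which 56 and 28 changed at least 2-fold. The largest fall was in Vsnl1, a neuronal calcium sensor, with a log2 fold change of -4.16 (SE 0.65, adjusted p = 0.0105), from 10.34 ± 0.50 (SD, n = 4) to 6.18 ± 0.21 (SD, n = 4). The largest rise was in Fetub, a secreted protease inhibitor, with 4.32 (SE 0.84, adjusted p = 0.0242), from 7.98 ± 1.26 (SD, n = 4) to 12.30 ± 0.75 (SD, n = 4).

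The interferon response list fell as a group by camera. Of its 26 measured members 15 fell, 0 rose and 11 did not pass, and 26 fell when adjusted over the list alone. The median log2 fold change was -1.62 (camera adjusted p = 3.45e-26, adjusted p = 0.309 with an estimated correlation), and fry gave an adjusted p of 0.00697. Among its members were the antiviral gene Mx2 at -2.14 (SE 0.32, adjusted p = 0.00897), Stat2, a transducer of interferon signals, at -1.65 (SE 0.23, adjusted p = 0.00707), Bst2, a viral restriction factor, at -1.56 (SE 0.25), and Oasl1 at -1.52 (SE 0.25). Oas2 (-2.85, SE 0.59), Zbp1 (-2.17, SE 0.43) and Ifit1 (-2.15, SE 0.45) fell too. Outside the list, Ifit3b (-2.43, SE 0.53) and Ddx60 (-2.23, SE 0.53), an antiviral helicase, fell. The list's mean log2 was 10.59 ± 0.29 (SD, n = 4) in nulliparous and 8.85 ± 0.52 (SD, n = 4) in parous WT tumours.

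**Figure D1:**
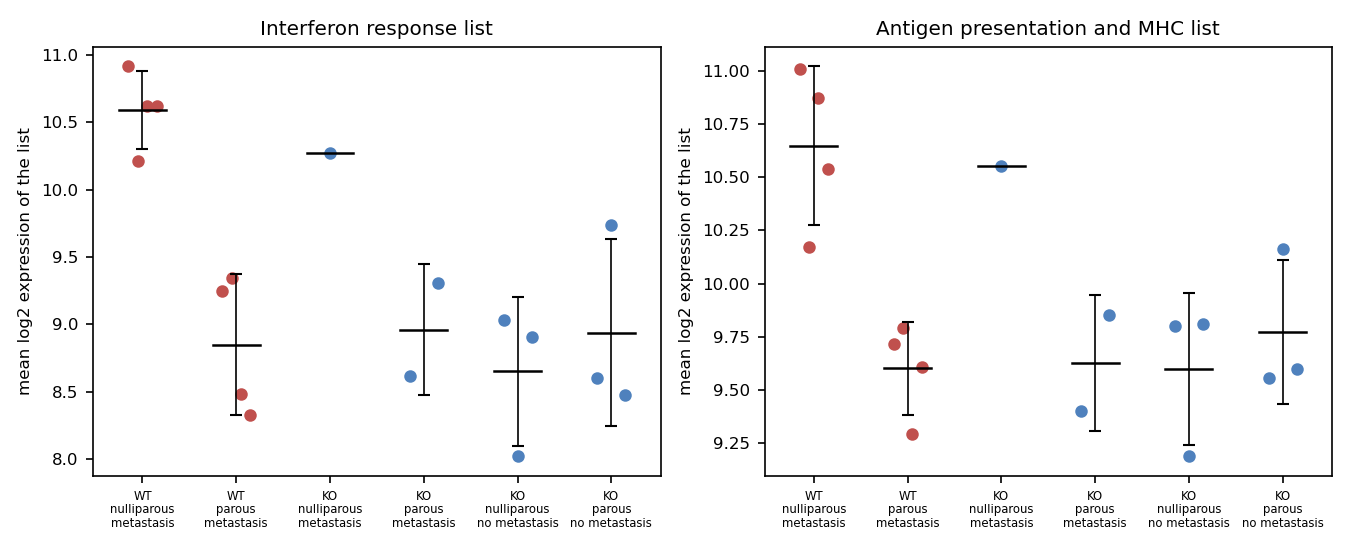
Mean log2 expression of the interferon response list (left) and of the antigen presentation and MHC list (right) in each of 17 samples, by group; points are samples, lines are group means and bars are SDs, and the KO nulliparous group with metastasis has 1 sample and no bar. The 4 nulliparous WT samples lie above the 4 parous WT samples in both lists, with interferon means of 10.59 and 8.85.

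The antigen presentation and MHC list also fell as a group by camera in the same contrast, but not with an estimated correlation. Of 15 measured members 7 fell and 8 did not pass, and 12 fell when adjusted over the list alone; the median was -1.02 (camera adjusted p = 2.08e-12, adjusted p = 0.309 with an estimated correlation), and fry gave 0.0109 as the adjusted p. The peptide transporter gene Tap1 stood at -1.84 (SE 0.31), the immunoproteasome subunit Psmb9 at -1.77 (SE 0.30), and the class I genes H2-Q4 and H2-M3 at -2.20 (SE 0.43) and -1.22 (SE 0.23), all with adjusted p under 0.05. Of 20 T and NK cell markers 2 fell, Nkg7 (-1.48, SE 0.34), a granule protein of cytotoxic cells, and Ncr1 (-0.40, SE 0.09), an activating receptor of NK cells; 9 fell when adjusted over the list alone (median -0.25, camera adjusted p = 2.23e-06, adjusted p = 0.582 with an estimated correlation). Without nulliparous WT replicate 3 the T and NK cell median was -0.14.

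Markers of other cell types also lay lower in parous WT tumours. In WT tumours macrophage markers had a median of -0.56 (17 of 18 below 0, camera adjusted p = 0.00146, adjusted p = 0.699 with an estimated correlation), fibroblast and matrix genes -0.61 (21 of 21 below 0, camera adjusted p = 4.37e-05, adjusted p = 0.699 with an estimated correlation) and skeletal muscle genes -0.82 (20 of 20 below 0, camera adjusted p = 0.00257, adjusted p = 0.751 with an estimated correlation). No member of these lists passed over all genes or when adjusted over the list alone. The muscle value rested on nulliparous WT replicate 1, at a mean log2 of 10.68 against 7.06 to 7.83 in the others of its group; without it the muscle median was 0.00036 and the call ended. Without parous WT replicate 3 the fibroblast and matrix median was -0.32. Adipocyte markers had a median of -0.35, and 1 of 18, the lipase gene Lipe, fell (-0.70, SE 0.14; camera adjusted p = 0.00497, adjusted p = 0.704 with an estimated correlation), the count also when adjusted over the list alone. Without nulliparous WT replicate 1 the adipocyte median was -0.10 and the call ended. Hypoxia and glycolysis genes had a median of 0.46 (20 of 23 above 0, camera adjusted p = 6.49e-06, adjusted p = 0.665 with an estimated correlation); 0 members rose over all genes and 1 when adjusted over the list alone. B and plasma cell markers had a median of -0.07 (camera adjusted p = 0.00879, adjusted p = 0.582 with an estimated correlation), milk and secretory differentiation genes -0.33 (camera adjusted p = 0.0118, adjusted p = 0.699 with an estimated correlation) and cytokines and chemokines -0.25 (camera adjusted p = 0.00257, adjusted p = 0.582 with an estimated correlation). Of these lists 0, 0 and 1 members fell over all genes and 0, 2 and 1 when adjusted over the list alone. The milk median was -0.53 without parous WT replicate 2, and the call ended without parous WT replicate 4 (-0.32) or nulliparous WT replicate 1 (-0.08); the B and plasma cell median was -0.12 without parous WT replicate 4. In the muscle list parous WT replicate 2 stood apart, at a mean log2 of 8.16 against 7.05 to 7.15 in the others of its group. In the hypoxia list replicate 2 of the nulliparous WT group stood apart, at a mean log2 of 11.89 against 10.84 to 10.85 in the others of its group.

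Among genes that rose in parous WT tumours were Pglyrp1 (3.38, SE 0.43), which encodes a peptidoglycan recognition protein, Dlgap1 (3.41, SE 0.63), Cpe (3.19, SE 0.64), a carboxypeptidase that processes prohormones, Mme (3.17, SE 0.50), the membrane peptidase neprilysin, and Cnmd (2.89, SE 0.39). Trpm3 (2.62, SE 0.50), Bche (2.56, SE 0.50), Hoxa5 (2.38, SE 0.52) and Cd177 (2.25, SE 0.49), a neutrophil surface protein, rose too, all with adjusted p under 0.05. The neutrophil list as a whole had a median of 0.01, with a mean log2 of 6.18 in parous and 6.21 in nulliparous WT tumours. The fatty acid elongase Elovl5 rose by 1.01 (SE 0.21). Among genes that fell were Epha2 (-2.42, SE 0.47), an ephrin receptor, the kinase Mtor (-0.77, SE 0.11), Sdhb (-0.78, SE 0.11) of respiratory complex II, and the cytokine Tnf (-0.46, SE 0.10).

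Fallen genes were concentrated on 2 chromosomes. Chromosome 4 carried 148 of the 370, though it holds 5.82% of placed genes (Fisher's exact test, adjusted p = 1.38e-84) and chromosome 2 carried 80, with 8.73% of placed genes (Fisher's exact test, adjusted p = 1.84e-13), while 0 and 1 genes rose there. Genes that share a chromosome are not independent within a tumour, so these p-values overstate the evidence. Epha2, Mtor and Sdhb lie on chromosome 4 and Zbp1 on chromosome 2. Over all 755 expressed genes of chromosome 4 the median log2 fold change was -0.40, with 87.9% below 0. The chromosome 4 level was -0.17 ± 0.07 (SD, n = 4) in parous and 0.24 ± 0.09 (SD, n = 4) in nulliparous WT tumours, a difference with an exact permutation p of 0.0286, the smallest 4 against 4 can give, and 0.190 when adjusted over 20 chromosomes. The same p and adjusted p were reached by chromosome 2, whose level was lower in parous tumours by a difference of -0.15, and by chromosome X, higher by 0.08. Off chromosomes 2 and 4, 142 genes fell and 106 rose. Risen genes were enriched on chromosomes 15 (12 of 747 tested genes, Fisher's exact test, adjusted p = 0.0105), 17 (13 of 936, adjusted p = 0.0105) and 3 (12 of 943, adjusted p = 0.0193), with the same dependence between genes; the level of chromosome 15 was 0.32 in parous WT replicate 4.

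**Figure D2:**
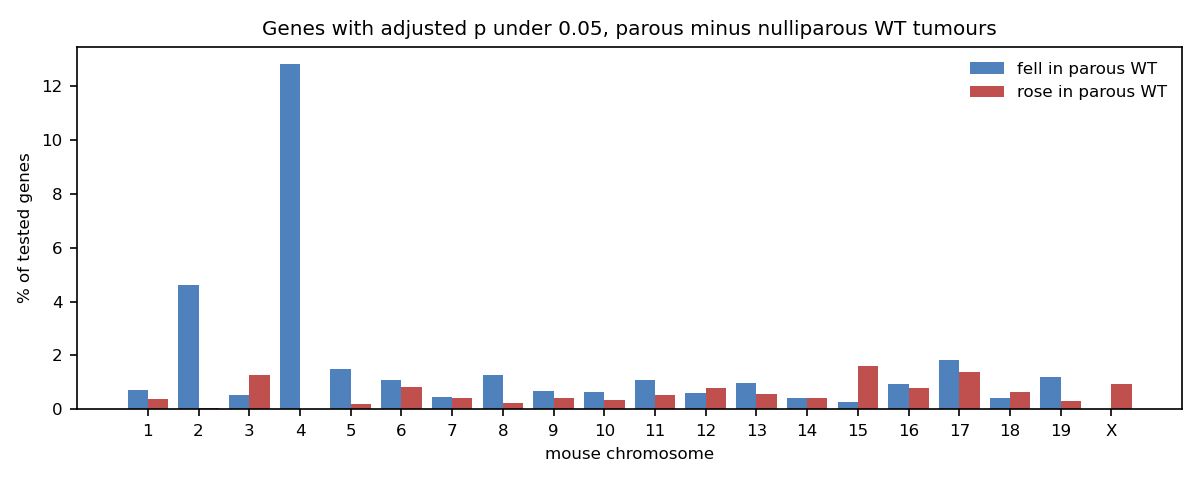
Share of tested genes of each mouse chromosome that fell or rose in parous against nulliparous WT tumours with metastasis (n = 4 in each group; limma, adjusted p under 0.05); bars start at 0. On chromosome 4, 12.8% of genes fell and 0 rose, and on chromosome 2, 4.62% fell.

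The count of 478 rested on several tumours. It was 57 without nulliparous WT replicate 4, 66 without replicate 1, 82, 85, 259 and 274 without parous WT replicates 3, 4, 1 and 2, and 770 without replicate 2 of the KO parous mice lacking metastasis, which shares the estimate of the spread. With the adipocyte and leukocyte list means as covariates 0 genes passed: the interferon median was then -0.78 (median SE 0.43) against -1.62 (median SE 0.41). Quantile normalization again moved the split to 152 higher and 275 lower genes.

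In KO mice without metastasis, parous and nulliparous tumours (n = 3 in each) did not differ in any gene at the threshold. Milk and secretory differentiation genes had a median log2 difference of 0.54 (19 of 21 above 0, camera adjusted p = 0.000213, adjusted p = 0.573 with an estimated correlation), and oxidative phosphorylation genes one of -0.09 (21 of 25 below 0, camera adjusted p = 6.54e-05, adjusted p = 0.573 with an estimated correlation). In both lists 0 members passed over all genes or when adjusted over the list alone. The milk median was 0.24 without parous replicate 2 and 0.32 without nulliparous replicate 2, and that of oxidative phosphorylation was -0.16, -0.05 and -0.14 without parous replicates 1 and 2 and nulliparous replicate 3. The interferon list, at 8.94 ± 0.69 (SD, n = 3) in parous and 8.65 ± 0.55 (SD, n = 3) in nulliparous tumours, was not called. Among the genes with the smallest p in each direction were Trex2 (0.26, SE 0.05), Samd5 (1.24, SE 0.31), Tmem223 (-2.23, SE 0.53) and Pop5 (-0.49, SE 0.11), each with adjusted p = 1 after rounding. By limma 0 genes passed and 655 had an unadjusted p under 0.05. In all, camera called 9 of 26 lists and 0 with an estimated correlation. Leaving out parous replicate 1 gave 2 genes, and leaving out parous replicate 3 or nulliparous replicate 2 gave 1 each.

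Whether parity acted differently in KO and WT was tested as the difference of these contrasts, in which metastasis status differs together with genotype. No gene passed. The smallest adjusted p by limma was 0.267, reached by genes such as Ogfr (0.88, SE 0.14), Kdm1a (0.77, SE 0.13), a histone demethylase, and Slfn1 (1.17, SE 0.20). Ogfr lies on chromosome 2 and Kdm1a on chromosome 4, where the fallen genes of parous WT tumours were concentrated. Both were among those fallen genes, at -0.83 and -0.82, while Slfn1 lies on chromosome 11. Dlgap1 stood at -4.76 (SE 0.96) and Pglyrp1 at -3.50 (SE 0.65), both with adjusted p = 0.268. The interferon list had a median difference of 1.93, with 26 of 26 members above 0 (camera adjusted p = 2.73e-24, adjusted p = 0.322 with an estimated correlation; fry adjusted p = 0.0559). No member passed over all genes, and 26 did when adjusted over the list alone. Antigen presentation and MHC genes had a median difference of 1.36 (camera adjusted p = 3.38e-12, adjusted p = 0.322 with an estimated correlation; fry adjusted p = 0.0559), with 0 of 15 passing over all genes and 11 when adjusted over the list alone. Across the 19938 genes, which are not independent replicates, the log2 differences of WT and KO had a Pearson r of -0.117 and a Spearman rho of -0.0725. By limma 0 genes passed, while 1922 had an unadjusted p under 0.05. Counts of 1, 1, 3 and 8 genes came without KO parous replicate 2, KO nulliparous replicate 2, KO nulliparous replicate 3 (all lacking metastasis) and nulliparous WT replicate 2.

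Over all 17 samples, adjusted for genotype and metastasis, parity gave no passing gene. The smallest adjusted p was 0.0690, reached by genes such as Vsnl1 (-3.18, SE 0.52), Cnmd (2.08, SE 0.32), and by Rere (-0.42, SE 0.06), Pex10 (-0.55, SE 0.09), Dffa (-0.42, SE 0.07) and Pank4 (-0.42, SE 0.07), the last 4 on chromosome 4. Vsnl1 had log2 values of 9.93 to 11.00 in the 4 nulliparous WT tumours and 9.83 in the lone nulliparous KO tumour with metastasis, and ran from 6.09 to 10.14 in the 3 nulliparous KO tumours without metastasis. The interferon list had a median of -0.92 (26 of 26 below 0, camera adjusted p = 4.34e-16, adjusted p = 0.565 with an estimated correlation), with 0 members passing over all genes and 21 when adjusted over the list alone. Antigen presentation and MHC genes had a median of -0.50 (camera adjusted p = 2.92e-08, adjusted p = 0.565 with an estimated correlation), with 0 and 7 passing, and one of -0.33 without nulliparous WT replicate 3. Macrophage, T and NK cell and B and plasma cell markers were lower in the same comparison, with 0 members passing either way. The median was -0.28 for macrophage (camera adjusted p = 0.0056, adjusted p = 0.805 with an estimated correlation), -0.13 for T and NK cell (3.01e-05 and 0.565) and -0.11 for B and plasma cell markers (0.00271 and 0.565). Without the nulliparous KO tumour with metastasis the macrophage (-0.24) and B and plasma cell (-0.04) calls ended. The macrophage call also ended without KO parous replicate 1 lacking metastasis (-0.24) and its median was -0.44 without replicate 2 of that group, while the T and NK cell median was -0.07 without nulliparous WT replicate 3. Fibroblast and matrix genes stood at a median of -0.37 (camera adjusted p = 3.35e-05, adjusted p = 0.596 with an estimated correlation) and hypoxia and glycolysis genes at 0.32 (camera adjusted p = 4.38e-05, adjusted p = 0.565 with an estimated correlation), with 0 members passing either way. Within KO mice without metastasis some of these lists went the other way with parity. Medians there were 0.26 for interferon, 0.13 for antigen presentation and MHC, 0.20 for macrophage, 0.08 for T and NK cell and 0.10 for B and plasma cell lists. The fibroblast and matrix list stood at -0.13 there and the hypoxia list at -0.04. In all, camera called 11 of 26 lists and 0 with an estimated correlation. By limma 0 genes passed and 2538 had an unadjusted p under 0.05. Counts moved to 4 without KO parous replicate 1 with metastasis, to 23 and 337 without KO parous replicates 1 and 2 lacking metastasis, and to 18 and 369 without KO nulliparous replicates 1 and 2 lacking it; with both arrays of the near-identical pair kept apart 55 genes passed, with array weights 781, and with all probe sets 39.

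Metastasis was compared in KO mice alone, since every WT mouse had it. Among parous KO mice, tumours with (n = 2) and without (n = 3) metastasis did not differ in any gene at the threshold. Hypoxia and glycolysis genes had a median log2 difference of 0.38, with minus without metastasis (21 of 23 above 0, camera adjusted p = 2.96e-07, adjusted p = 0.973 with an estimated correlation), and skeletal muscle genes one of -0.99 (20 of 20 below 0, camera adjusted p = 0.000287, adjusted p = 0.973 with an estimated correlation); 0 members passed over all genes or when adjusted over the list alone. The hypoxia call ended without the averaged replicates 2 and 3 with metastasis (median 0.15), and its median was 0.60 without replicate 1 lacking metastasis; the muscle call ended without replicate 3 lacking metastasis (-0.63). Gart, a purine synthesis enzyme on chromosome 16, stood at -0.64 (SE 0.12, adjusted p = 0.967) and Kiss1r, the kisspeptin receptor, at -0.57 (SE 0.12, adjusted p = 0.967). In all, camera called 7 of 26 lists and 0 with an estimated correlation. With limma 0 genes passed and 805 had an unadjusted p under 0.05. Leaving out replicate 1 with metastasis gave 2 genes, the averaged replicates 2 and 3 gave 5, and nulliparous WT replicate 2 gave 1.

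With all samples and adjustment for genotype and parity, metastasis also gave no passing gene. Only KO tumours differ in metastasis status, and among the nulliparous ones 1 had metastasis. The fit shares 1 parity term between KO and WT, so the parity difference of WT tumours also enters the metastasis values. For the interferon list the parity medians were -1.62 in WT mice and 0.26 in KO mice without metastasis. By list means the latter direction rested on 1 parous tumour, as given above. Proliferation genes had a median of -0.41, with 28 of 28 members below 0 (camera adjusted p = 6.27e-14, adjusted p = 0.652 with an estimated correlation); 0 passed over all genes and 3 when adjusted over the list alone. Their median was -0.21 without the nulliparous tumour with metastasis and -0.63 without the averaged pair. Interferon response genes had a median of 0.74, with 26 of 26 above 0 (camera adjusted p = 9.24e-14, adjusted p = 0.652 with an estimated correlation), and 0 passed either way; without the nulliparous tumour with metastasis the median was 0.58. Among KO tumours the interferon mean log2 was 10.27 in that tumour against 8.65 in nulliparous tumours without metastasis (n = 3), but 8.96 (n = 2) against 8.94 (n = 3) in parous ones with and without. Leukocyte markers were higher in the same tumour than in nulliparous KO tumours without metastasis. List means were 7.20 against 6.40 for B and plasma cells and 6.75 against 6.35 for T and NK cells. For macrophages they were 9.54 against 8.57 to 9.24 in single tumours, but KO parous replicate 2 lacking metastasis stood higher, at 9.895. Camera called these 3 lists for metastasis, with medians of 0.13 (adjusted p = 4.7e-08, 0.652 with an estimated correlation), 0.07 (adjusted p = 0.00351, 0.692 with an estimated correlation) and 0.16 (adjusted p = 0.0366, 0.719 with an estimated correlation) and 0 members passing either way. Without the nulliparous tumour with metastasis the calls ended and the medians were -0.04, 0.01 and 0.01. The macrophage call also ended, with medians of 0.04 to 0.20, without KO parous replicate 1 with metastasis, KO parous replicate 1 or 3 or KO nulliparous replicate 1 or 2 lacking it, or nulliparous WT replicate 1. Its median was 0.40 without KO parous replicate 2 lacking metastasis. Without the averaged pair the 3 medians were 0.20, 0.12 and 0.32, and that of T and NK cells was 0.12 without KO parous replicate 1 and 0.04 without KO nulliparous replicate 3, both lacking metastasis. Skeletal muscle genes had a median of -0.80 (camera adjusted p = 6.37e-05, adjusted p = 0.685 with an estimated correlation), with 0 members passing either way, and of -0.52 without KO parous replicate 3 lacking metastasis. In all, camera called 14 of 26 lists and 0 with an estimated correlation. The smallest adjusted p, 0.196, belonged to Lrrk1 (-0.38, SE 0.06), a kinase gene, and Gart (-0.55, SE 0.09). By limma 0 genes passed and 999 had an unadjusted p under 0.05. With both arrays of the near-identical pair kept apart Lrrk1 and Gart passed, 2 genes in all, and without the averaged pair 1 did. The fit with both arrays apart counts what may be 1 tumour as 2 samples. Gart lies on chromosome 16, whose last window was low on these arrays, at -0.45 and -0.44.

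Levels of neighbouring genes varied together from tumour to tumour. In 15 of 17 samples at least 1 of 120 windows of consecutive genes lay 0.2 or more from the mean of the samples. Such windows lay on 9 of the 20 chromosomes.

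**Figure D3:**
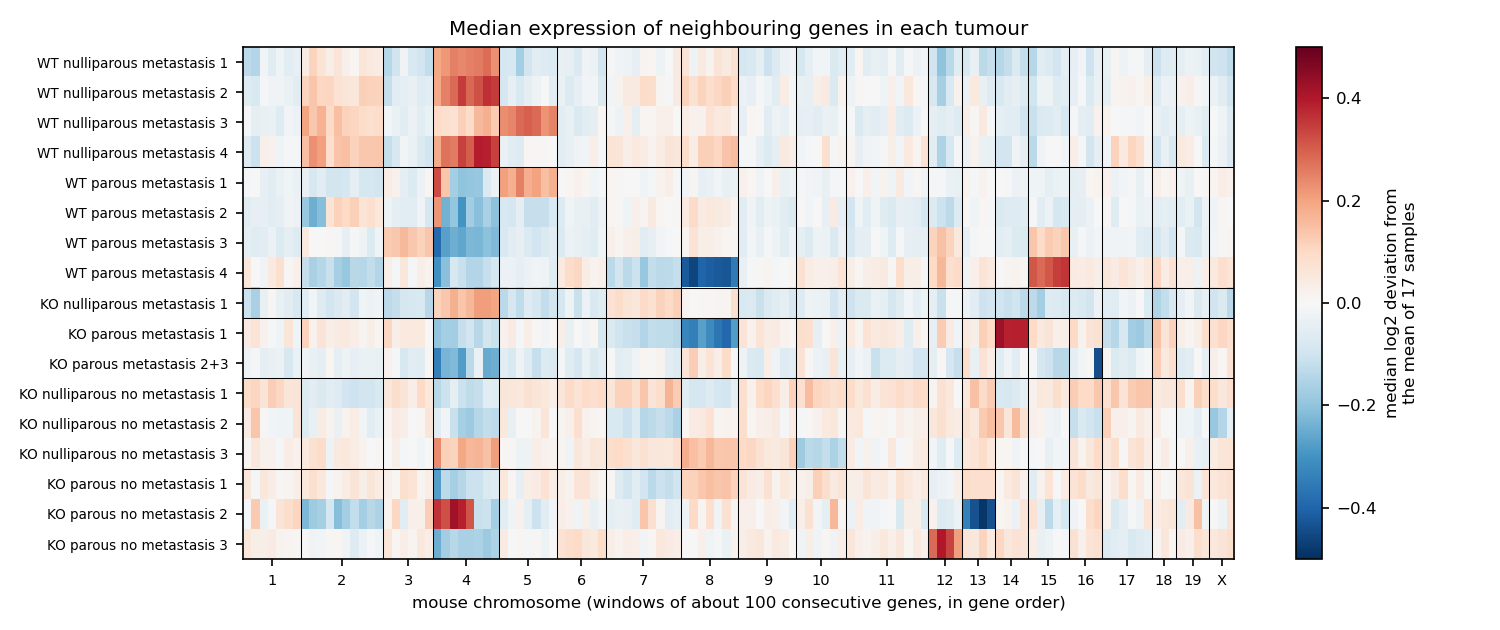
Median log2 deviation of windows of 93 to 110 consecutive genes (columns, by mouse chromosome in gene order) from the mean of 17 samples, in each sample (rows, by group, KO and WT); red is higher and blue is lower. All 4 nulliparous WT samples are red along chromosome 4, with a mean level of 0.24, and the 4 parous WT samples are mostly blue there, with -0.17.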

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

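The tests of chromosome windows, of the permutation p over chromosomes, of the placement of interferon members, of the window profiles of the near-identical arrays and of lists with a sample left out were chosen after those values were seen; the composition covariates and the counts of splits were fixed beforehand. Of 4 tests tried on the chromosome 4 pattern 3 are weighed here. A batch of arrays that follows parity was tried first through the spread of KO levels within a group, at most 0.32. That test was replaced by the permutation p because its bound had been set with the values in view. The permutation p cannot test such a batch, which would follow the same split of tumours, and no batch label is given. A batch of that kind was therefore not excluded.

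In WT mice the parity contrast called 478 genes, and 1 of the 35 splits of the 8 tumours, the real split, gave as many. The highest other split gave 0. That share of 2.86% is the smallest that 35 splits can give, and it is not adjusted over the comparisons tested this way. It argues against a random grouping of these tumours without such adjustment, and does not exclude it. In the other 5 comparisons tested this way the real split gave 0 genes, so every split gave as many by construction and the counts cannot exclude chance or speak for it. These were all 75 splits of genotype in the additive fit (highest other 18), all 40 of metastasis status (highest other 43), and all 100 drawn splits of parity in the additive fit (highest other 5). For parity in KO mice without metastasis they were all 10 splits (highest other 2), which are also too few for a share under 0.05. For the difference of the parity contrasts they were all 100 drawn splits, and the highest other gave 854, which points to some structure of the samples; 9 of the other drawn splits gave any gene, and what they follow was not tested.

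Genes of chromosome 4 were lower in tumours of parous WT mice, with a median of -0.40. An array-wide technical trend would move other chromosomes as far, and 7 of the 8 windows of chromosome 4 lay below the lowest window of all other chromosomes (-0.28). Chromosome 4 was picked for its fallen genes in the same data, so this rank carries little weight against such a trend. A different share of non-tumour cells stays open: with adipocyte and leukocyte covariates the median was -0.30, and the 148 fallen genes went from -0.66 (median SE 0.13) to -0.54 (median SE 0.18) with 148 still below 0, so the calls ended on a smaller difference and a wider error. Tumours that differ by chance in chromosome 4 also stay open: the exact permutation p of 0.0286, the smallest 4 against 4 can give, was also reached by chromosomes 2 and X and became 0.190 when adjusted over 20 chromosomes, where 1 chromosome alone could not pass. A batch of arrays that follows parity stays open too, without a test of it here. A difference in chromosome copies that goes with parity in WT mice may underlie the pattern, which expression alone does not measure. In KO mice without metastasis the level was -0.05 ± 0.17 (SD, n = 3) in parous and -0.02 ± 0.15 (SD, n = 3) in nulliparous tumours. In KO mice with metastasis it was -0.18 in parous (n = 2) and 0.17 in the lone nulliparous tumour.

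The interferon list was lower in the same tumours. Placement of its members on the shifted chromosomes is argued against, since 2 of the 15 called members lie on chromosomes 2 and 4. More leukocytes in tumours of nulliparous mice may account for a part. With the composition covariates the median was -0.78 (median SE 0.43), against -1.62 (median SE 0.41), with 26 of 26 members still below 0 and 0 called instead of 15. T and NK cell means, part of the leukocyte covariate, ran from 6.42 to 6.51 in parous and 6.56 to 7.35 in nulliparous WT tumours. A covariate that goes with parity can take out a parity difference of any origin, so the smaller median does not show a share of leukocytes. Macrophage, T and NK cell markers were lower too, and interferon genes are also expressed by leukocytes, so these covariates take out a response shared by tumour and immune cells as well. Parity itself stays open, as does a batch of arrays that follows it.

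The KO parous replicates 2 and 3 with metastasis correlated at 0.963 in their profiles over 120 windows, above every other pair of arrays. The next were nulliparous WT replicates 1 and 2 at 0.953. With chromosome 4 left out the value was 0.950, against 0.890 for the highest other pair. The KO pair was picked for the closeness of the same gene values, so this rank carries little weight of its own. Both arrays had a low last window of chromosome 16, at -0.45 and -0.44, where all other arrays lay between -0.11 and 0.14. They may come from 1 tumour measured on 2 arrays; separate parts of a tumour cannot be excluded, and no biological explanation was tested.

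By the test for a far sample, 3 of 60 groups of values stood out, the number chance gives at 1 in 20. In parous WT replicate 2 the skeletal muscle list had a mean log2 of 8.16 against 7.05 to 7.15 in its group, and the ERBB receptor, ligand and MAPK feedback list one of 9.81 against 10.09 to 10.12. In nulliparous WT replicate 2 the hypoxia and glycolysis list stood at 11.89 against 10.84 to 10.85.

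The parity contrast differed between KO and WT for 16 of 26 lists by camera, and for 0 with an estimated correlation (lowest adjusted p = 0.322) or by fry (lowest adjusted p = 0.0559). The camera call ended for 9 of the 16 when at least 1 sample was left out, 7 of them without KO parous replicate 2 lacking metastasis; without nulliparous WT replicate 1 the calls on skeletal muscle (median 0.47) and adipocyte genes (0.13) ended. The median differences were 1.93 for interferon response, 1.36 for antigen presentation and MHC, 1.22 for milk and secretory differentiation, 1.19 for skeletal muscle, 0.70 for macrophage, 0.55 for fibroblast and matrix, 0.49 for basal and myoepithelium, 0.43 for matrix proteases, 0.40 for cytokines, 0.38 for endothelium, 0.37 for adipocyte, 0.36 for mesenchymal regulators, 0.30 for T and NK cell, 0.18 for B and plasma cell, -0.11 for oxidative phosphorylation and -0.49 for hypoxia and glycolysis genes.

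Outside the named genes, 228 of 12146 probe sets with no gene and 22 of 1621 with several genes passed in the parity contrast of WT mice when all probe sets were tested.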

How the results depend on the processing

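The fits without genes of chromosomes 2 and 4, the list tests with each sample left out, and the choice of 17 samples over the 18 arrays fixed beforehand, which makes the fit with both arrays of the pair kept apart an alternative, came after the data were seen. The parity contrast of WT mice was the only comparison with passing genes, 478, and its count ran from 57 to 770 when each sample was left out in turn. It was 741 with all probe sets, 1718 with array weights, 878 with only the 2 groups compared, 963 at an adjusted p under 0.1 and 84 at 2-fold. It was 231 without genes of chromosome 4, 101 without chromosomes 2 and 4, which tested fewer genes, and 0 with composition covariates, as weighed above. Apart from the replicate block, the remaining alternatives gave counts within 1.5 times of 478; array medians subtracted shared 420 of its 429 calls, quantile normalization again 381 of 427, and both arrays of the pair kept apart 478 of 628. With the replicate number as a block the count was 212; the numbers pair no samples, since 9 of 31 same-numbered pairs correlated above 0.1 and 3 of 17 arrays were closest to their own number. Of the 34 named genes past the threshold there 18 still passed with the block, and the other comparisons stayed at 0 genes with it. Of the same 34 genes 10 still passed without nulliparous WT replicate 1, and 0 with composition covariates. The number was 11 without nulliparous WT replicate 4 or parous WT replicates 3 or 4, and 26 to 34 without each other sample. For parity in the additive fit, 0 genes became 39 with all probe sets, 781 with array weights, 76 at an adjusted p under 0.1, 55 with the pair kept apart, and 0 to 369 when each sample was left out. For the other comparisons with 0 genes, leaving out each sample gave 0 to 17 for genotype among parous mice with metastasis, 0 for genotype in the additive fit, 0 to 2 for parity in KO mice, 0 to 8 for the difference of parity contrasts, 0 to 5 for metastasis in parous KO mice and 0 to 1 for metastasis in the additive fit, which gave 2 with the pair kept apart. No other alternative gave them a passing gene. Of 208 list tests 81 passed by camera, 0 with an estimated correlation and 2 by fry, and 68 to 89 by camera when each sample was left out, which moved the medians or ended the calls of single lists. Of 3403 values of named genes under alternatives, 27 reversed, 21 of them with a sample left out. All were of Snai2 or Erbb2 in comparisons of parity or metastasis, where neither passed and both lay near 0. When each sample was left out, Snai2 ran from -0.055 to 0.028 for parity in the additive fit, -0.12 to 0.041 in WT mice, -0.21 to 0.023 in KO mice, -0.18 to 0.053 for the difference of parity contrasts, -0.016 to 0.21 for metastasis in parous KO mice and -0.082 to 0.077 for metastasis in the additive fit. Erbb2 log2 fold change ran from -0.0083 to 0.060 for parity in the additive fit and -0.089 to 0.054 in KO mice. With array weights Snai2 stood at 0.0011 for parity in WT mice and 0.016 for metastasis in the additive fit, and Erbb2 at 0.048 for parity in KO mice and 0.010 for the difference of parity contrasts. Snai2 stood at 0.0049 for parity in WT mice with composition covariates and at -0.0063 for metastasis in parous KO mice with the replicate block. Apart from fewer genes or samples, the cause was not tested. Dim genes such as Snai2 may lie near background, where small differences can be lost, but the background level was not measured here.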

Other observations

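The levels of whole chromosomes in single tumours and the test of the relation of interferon and chromosome 4 levels were chosen after the values were seen.

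Whole chromosomes stood apart in single tumours. In KO parous replicate 1 with metastasis, chromosome 8 had a level of -0.32 and chromosome 14 one of 0.40. In KO parous mice lacking metastasis, replicate 2 had -0.43 on chromosome 13 and replicate 3 had 0.31 on chromosome 12. Parous WT replicate 4 had -0.42 on chromosome 8 and 0.32 on chromosome 15, and nulliparous WT replicate 3 had 0.25 on chromosome 5. Chromosome 4 stood at -0.22 in the averaged KO pair and at -0.25 in parous WT replicate 3. It stood at 0.23, 0.30 and 0.31 in nulliparous WT replicates 1, 2 and 4. Genes named above for genotype, such as Ppp3cc and Slc39a14, lie on chromosome 14, and Gart lies on chromosome 16, where the averaged pair had its low window.

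A hypothesis is that the interferon level of a tumour follows its chromosome 4 level. The WT tumours fall into 2 clusters by parity with 4 in each, so no value is given over them. Within the 9 KO samples Pearson's r was 0.62 (exact permutation p = 0.072, 95% interval -0.07 to 0.91) and Spearman's rho 0.47 (exact permutation p = 0.213); adjusted over the 3 sets of samples for which it was computed the values were 0.072 and 0.213. Without the 2 samples farthest on the chromosome 4 axis r was 0.53. The relation was not shown and could not be excluded with 9 samples.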
